A study of Mus musculus with 43 samples.

How the data were processed

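Total RNA of 43 frozen mouse high-grade astrocytomas was labelled with Cy5 and hybridised, together with Cy3-labelled Stratagene whole mouse reference RNA, to Agilent 4x44K arrays (coordinates of build mm9, 13 slides), with no dye swap. Per the file headers, the scanner files hold the mean spot signal and the median local background of both channels as intensity, from Agilent Feature Extraction 10.5.1.1 for batch 1 and 10.7.3.1 for batches 2 and 3. The same files hold, per the file headers, a log10 ratio of tumour over reference after that software's background and dye normalisation. The deposited values are log2 of tumour over reference, for 31810 probes. In that table each of 43 columns correlated best with its own array (median r across probes 0.890, lowest 0.799), and its batch means spread less than those of the scanner log ratios (0.0490 against 0.185), but how the authors adjusted it is not stated.

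The comparisons start from the intensities. Background was corrected with normexp (offset 50) and ratios were normalised by loess within each array, control spots carrying no weight, in limma 3.58.1 under R 4.3.3 with the data.table package, version 1.17.8. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Spots marked as outliers by the scanner software were left out (0.683% of spots), and 0 spots were saturated. Of 39429 probes, 34706 were well above background in the tumour channel on at least 8 arrays and were kept. Probes took their gene symbol through a RefSeq accession where one was given (26055 probes) and otherwise the name in the file (13374 probes). Each gene was represented by its brightest probe, 5551 genes having more than 1, and 28006 genes were tested after 12 with more than 8 missing values were left out. Median signals ran from 68.7 to 738 in the tumour channel and from 150 to 391 in the reference channel. On 3 arrays, all in batch 2, fewer than 70% of the spots were well above background. They are called dim below.

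Genes were tested with limma's moderated statistic on the log2 ratio, with the mouse as a random block (within-mouse correlation 0.204 in the model of genotype and location) and Benjamini-Hochberg adjusted p under 0.05 as the threshold. A log2 value is given with its standard error. Genotype and location were estimated together with batch. Subtype was fitted with batch, diagnosis and survival each with genotype, location and batch, and the dependence of the BS difference on genotype in TR and TRPhet tumours with batch. A fold compares fitted values, and a count such as 16 of 18 is the number of tumours of the first group on the side of the change from the second group's mean. Survival was compared per mouse by two-sided exact permutation, label tables by Fisher's exact test, list means within batches by two-sided exact permutation, and correlations by 100000 permutations. With each of 11 comparisons, the count of genes was set against 100 splits of the tumours, the real one included.

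In all, 27 gene lists were fixed. They were mesenchymal, proneural, neural and classical tumour genes, proliferation, antigen presentation and interferon, hypoxia, MAPK output, FoxO targets, immediate early genes, and hindbrain, telencephalon and diencephalon patterning. The cell type lists were microglia and macrophage, T and NK cell, astrocyte, oligodendrocyte precursor, mature oligodendrocyte, neuron, neuroblast, endothelial, mural, ependymal, choroid plexus, olfactory bulb neuron, cerebellar granule neuron and red blood cell markers. They were tested in 13 contrasts with camera at a preset correlation of 0.01, with p adjusted over the lists of a contrast, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way. Named genes are, in each contrast, the 10 largest rises and 10 largest falls past the threshold (accessions, clones and gene models left out), all where fewer pass and the 4 with the smallest p where none passes, plus up to 4 passing members of each list whose set test passes or with at least 3 passing members. Genotype contrasts add Rb1, Rbl1, Rbl2 and Trp53. Results on 5 further single genes are not reported here. The rule named 255 other genes. Probes of the same gene disagreed in sign in 8 of its entries. The lists, the tests and this rule were chosen before the data were examined. The limit on missing values, the route from probe to gene symbol and the exact patterns of names left out were set once the files were open.

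Alternatives were no background subtraction, the log ratio of the scanner software, quantile scaling between arrays, the deposited table, no filter on dim probes or a filter at 22 arrays, the mean of all probes of a gene, no mouse block or slide as block, 1 tumour per mouse, no batch term, each batch alone, other covariates, TRPhet or BS tumours alone, and the location in the title for 1 tumour whose title and characteristic differ. Settings added after seeing the data left out the 3 dim arrays, read the labels of 2 slides of batch 1 in reverse order of array position, left out the 8 tumours of these slides, and took 2 pairs of tumours unlike in sex-linked genes as 4 mice or left them out. The pipeline was tested on simulated data in which 200 genes were changed in the tumours' reordered residuals, in 3 draws. Of changes of log2 1 it found 84.0% for TRPnull against TR, 95.3% for BS, 91.3% for S2, 93.3% for diagnosis, 89.3% per month of survival and 38.0% for the dependence of BS on genotype. False calls in these ran from 0.187% (BS) to 5.66% (diagnosis). The highest share among all simulated comparisons was 7.31%, for OFB against the other 3 locations.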

Results

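RNA was measured in 43 high-grade astrocytomas of mice, 1 array per tumour, as the log2 ratio of the tumour signal to a common whole mouse reference RNA hybridised to the same array. The labels put 9 tumours in genotype TR, 26 in TRPhet and 8 in TRPnull, and they put 18 in location BS, 8 in Ctx, 8 in Di and 9 in OFB. They gave an expression subtype (18 S1, 8 S2, 17 S3), a diagnosis (31 GBM, 12 A3) and the survival of the mouse in months. The codes are read here from knowledge of such mouse models, not from the labels. T stands for an antigen that inactivates the Rb family. BS is the brainstem, Ctx the cortex, Di the diencephalon, OFB the olfactory bulb, GBM glioblastoma and A3 anaplastic astrocytoma. The tumours came from 36 mice, 7 of which gave 2 tumours at different locations. The arrays were scanned in 3 batches of 16, 13 and 14 tumours. All 6 TR tumours in BS lay in batch 1, and batch 2 held no TR tumour. There was no normal brain, so every value compares tumours with tumours. Between 57.1% and 90.0% of the spots on an array were well above local background in the tumour channel, and the number of arrays limits the precision.

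The first question was whether the genotypes differed in survival. Survival was 2.56 ± 0.614 months in TRPnull mice (SD, n = 7), 3.92 ± 0.467 months in TRPhet mice (SD, n = 21) and 4.33 ± 0.462 months in TR mice (SD, n = 8). Survival was shorter in TRPnull than in TR mice by a mean difference of -1.77 months (two-sided exact permutation test, adjusted p = 0.000233) and shorter than in TRPhet mice by -1.36 months (exact permutation, adjusted p = 1.52e-05). TRPhet mice differed from TR mice by -0.411 months (exact permutation, adjusted p = 0.0438). That last difference was -0.43 months between medians, with p = 0.119 in the exact permutation test, so it rests on the choice of the mean. The survival tests held no batch term. TRPnull mice with a tumour in batch 1 ran from 3.12 to 3.25 months, and the other TRPnull mice from 1.91 to 2.33. Among mice with a tumour in batch 1, TR mice ran from 3.52 to 4.93 months and TRPhet mice from 3.68 to 4.7. The difference of TRPhet from TR mice therefore cannot be told from batch.

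**Figure D1:**
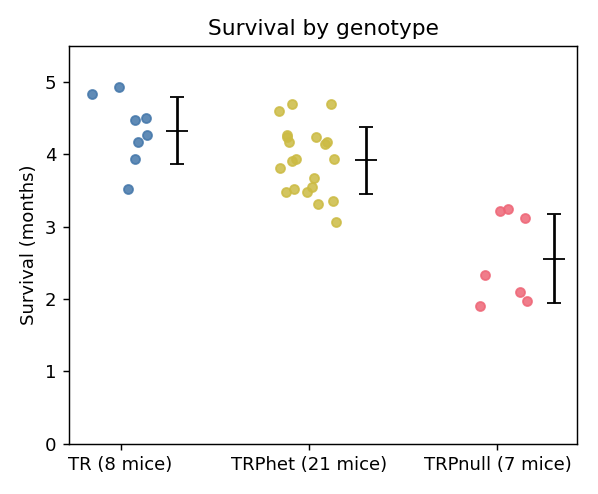
Survival in months (linear axis from 0) of each mouse by genotype, with the mean and SD beside the points. All 7 TRPnull mice lie between 1.91 and 3.25 months, and the 8 TR mice between 3.52 and 4.93 months.

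The second question was whether the expression subtype goes with location, genotype or diagnosis. Of the 18 BS tumours 13 were S1, 2 S2 and 3 S3, while 5 of the 25 tumours elsewhere were S1. Of the 8 Di tumours 6 were S3, and the 9 OFB tumours held 1 S1, 4 S2 and 4 S3. The 8 Ctx tumours held 3 S1, 1 S2 and 4 S3. Subtype and location were associated (Fisher's exact test, p = 0.00723, and p = 0.0432 with 1 tumour per mouse). Subtype was not found to be associated with genotype (Fisher's exact test, p = 0.616, and p = 0.0531 with the labels of 2 slides of batch 1 read in reverse order, a setting chosen after the values were seen) or with diagnosis (p = 1), and genotype was not found to be associated with location (p = 0.175). If the subtypes were defined on expression in these tumours, their tie to location restates expression. Within batch 2 all 5 BS tumours and 0 of 8 others were S1 (Fisher's exact test, p = 0.000777), and within batch 3 all 5 BS and 1 of 9 others (exact p = 0.003). Within batch 1, 3 of 8 BS tumours and 4 of 8 others were S1 (exact p = 1).

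The genotype comparisons asked which genes differ among TR, TRPhet and TRPnull tumours. Genes of the Rb family did not differ between TRPnull and TR tumours by the test. Rb1, the retinoblastoma gene, lay at log2 0.29 ± 0.19 (limma adjusted p = 0.733) and its relatives Rbl1 at 0.42 ± 0.27 (adjusted p = 0.716) and Rbl2 at -0.08 ± 0.22. Trp53, which no label names as altered, lay at 0.02 ± 0.20. The probes of Rbl1 disagreed in sign, and the values of Rbl2 and Trp53 changed sign under other settings. An antigen that inactivates the Rb family acts on its proteins, so these RNA levels do not measure its action. T also stands in all 3 genotype codes, so by that reading the genotypes share the antigen and these contrasts do not vary it.

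**Figure D2:**
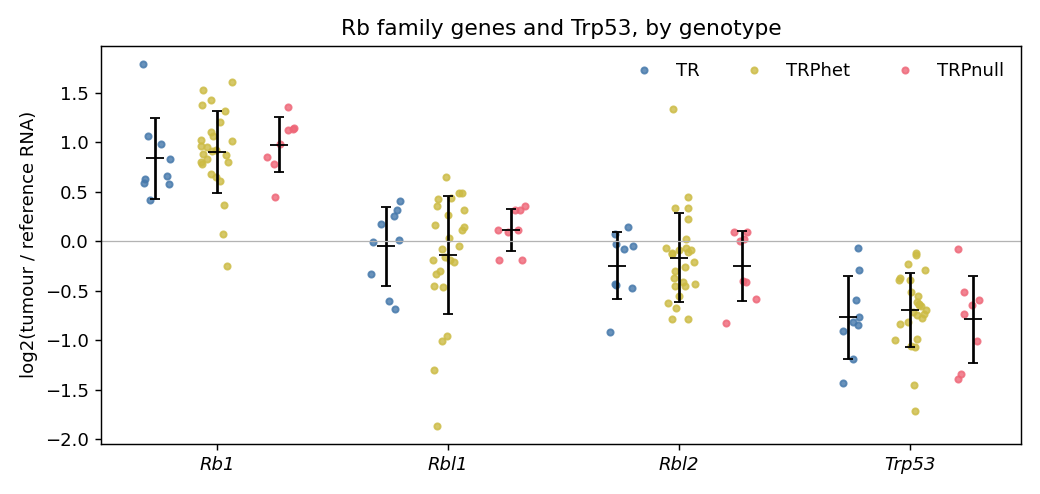
Log2 ratio of tumour to reference RNA for Rb1, Rbl1, Rbl2 and Trp53 in each of 9 TR, 26 TRPhet and 8 TRPnull tumours, with the mean and SD. The Rb1 means were 0.84 (SD 0.41, n = 9) in TR and 0.98 (SD 0.28, n = 8) in TRPnull tumours, and their SDs overlap.

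Across all genes, 1 gene passed, in TRPhet against TR tumours only, and 6 of 100 splits of the tumours, the real one included, gave as many. Pcdh19, an X-linked protocadherin of neurons and neural progenitors (chromosome X, probe at 130122356 to 130122415, build mm9), fell in TRPhet against TR tumours by log2 -1.42 ± 0.20 (adjusted p = 0.000399). Its means were -1.68 (SD 0.80, n = 26) and -0.75 (SD 0.73, n = 9), and 23 of 26 TRPhet tumours lay below the TR mean. With the labels of 2 slides of batch 1 read in reverse order, a setting chosen after the values were seen, its difference was log2 -0.90 (adjusted p = 0.554), and within BS tumours no gene passed. Between TRPnull and TR tumours limma called 0 genes, with 2212 at an unadjusted p under 0.05 against 1400 that chance alone would give, and between TRPnull and TRPhet it called 0, with 1573. The genes of smallest p in TRPnull against TR were Lcor, a nuclear receptor corepressor, at log2 -0.75 ± 0.13 (adjusted p = 0.0626), and Zfp292 at -0.98 ± 0.20. Next were Rnls, which encodes renalase, at 0.84 ± 0.17 (adjusted p = 0.155), and Cdh19, a cadherin of glial and Schwann cells, at 1.80 ± 0.38. Against TRPhet they were Ogfr at log2 0.52 ± 0.11 (adjusted p = 0.484), Ccdc154 at 0.36 ± 0.08, Rnls at 0.60 ± 0.14 and Olfr30 at 0.20 ± 0.05. Rnls passed with the reversed labels (log2 0.98, adjusted p = 0.00797), whereas Lcor then had log2 -0.45 (adjusted p = 0.982).

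Gene lists told the genotypes apart only under the preset correlation. Proliferation genes averaged log2 0.38 higher in TRPnull than in TR tumours, with 0 of 35 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 2.14e-05, adjusted p = 0.623 with an estimated correlation). Against TRPhet tumours they averaged 0.28 higher (camera adjusted p = 1.74e-06, adjusted p = 0.693 with an estimated correlation). Microglia and macrophage markers averaged 0.37 higher in TRPnull than in TR tumours (camera adjusted p = 0.000150, adjusted p = 0.487 with an estimated correlation). Antigen presentation and interferon genes averaged 0.44 (camera adjusted p = 0.00119, adjusted p = 0.623 with an estimated correlation), and endothelial markers 0.35 (camera adjusted p = 0.00119, adjusted p = 0.487 with an estimated correlation), with 0 of either list adjusted over the list alone. Before adjustment for location and batch the antigen presentation and interferon means ran the other way, at 0.902 in TR and 0.810 in TRPnull tumours (0.515 without TRPnull replicate 4, which stood apart). Unadjusted microglia and macrophage means were 1.06 in TR and 1.09 in TRPnull tumours (1.01 without that replicate). Those of proliferation were -0.222 and -0.0898 (-0.162 without it), and those of endothelial markers 1.57 and 1.69 (1.59 without it). The hindbrain list lay at 0.90 in TRPnull and 0.76 in TRPhet tumours against TR, and the telencephalon list at -0.83 and -0.78. All 4 of these camera calls were lost, with adjusted p = 0.487, 0.503, 0.487 and 0.457 with an estimated correlation. With the reversed labels of 2 slides these patterning differences were 0.05, -0.15, 0.16 and 0.28.

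The location comparison asked which genes mark tumours of the brainstem. Genes that pattern the hindbrain rose in the 18 BS tumours against the mean of Ctx, Di and OFB. Hoxb2, a homeobox gene of the rhombomeres (chromosome 11, probe at 96215122 to 96215181, mm9), rose by log2 2.78 ± 0.73 or 6.87-fold (adjusted p = 0.0164, 11 of 18 above the mean of the other 25 tumours). The neighbouring Hoxb4 rose by 2.22 ± 0.51 and Hoxb3 by 2.20 ± 0.66, and Hoxa3 by 2.01 ± 0.55. Pax3, a paired-box gene of the dorsal neural tube, rose by 2.71 ± 0.50 (adjusted p = 0.00174). Nr2e1, a nuclear receptor of forebrain progenitors (chromosome 10, probe at 42281826 to 42281885), fell by log2 -1.37 ± 0.40 or 2.58-fold (adjusted p = 0.0265, 13 of 18 below). Tbr1 of cortical neurons (-1.71 ± 0.54), whose probes disagreed in sign, also fell. C1ra, a complement protease, rose by 2.52 ± 0.38 or 5.72-fold (adjusted p = 0.000331, 16 of 18 above). Other rises were Car6 (2.59 ± 0.53), Thbs1, a matrix glycoprotein (2.50 ± 0.61), Dcn, which encodes decorin (2.15 ± 0.49), Casp4 (2.11 ± 0.41) and Plac8 (2.09 ± 0.40). Falling genes with synaptic or neuronal roles were Syt13 (-1.89 ± 0.40), Rasgrp1 (-1.88 ± 0.60), Nrn1 (-1.87 ± 0.36), Ptpn5 (-1.82 ± 0.58) and Kcnd2 (-1.80 ± 0.44), beside Celf3 (-1.88 ± 0.49) and Tmeff1 (-1.87 ± 0.44). In all, 2394 of 28006 genes passed, 1590 higher and 804 lower in BS, of which 279 and 98 differed at least 2-fold.

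Immune genes rose with the hindbrain genes in BS tumours. Of the antigen presentation and interferon list 11 of 18 rose (17 adjusted over the list alone, camera adjusted p = 5.52e-14, adjusted p = 0.178 with an estimated correlation). Among them were H2-K1, a class I histocompatibility antigen (1.49 ± 0.25, adjusted p = 0.00105), its partner B2m (1.19 ± 0.25) and the immunoproteasome subunits Psmb9 (1.40 ± 0.27) and Psmb8 (1.18 ± 0.24). Of the T and NK cell markers 9 of 13 rose (10 adjusted over the list alone, camera adjusted p = 2.30e-09, adjusted p = 0.178 with an estimated correlation), with the chemokine Ccl5 at 1.61 ± 0.31 and the T-cell surface gene Cd2 at 1.27 ± 0.29. Of the microglia and macrophage markers 10 of 20 rose (13 adjusted over the list alone, camera adjusted p = 9.14e-10, adjusted p = 0.201 with an estimated correlation), with the protease Ctss at 1.03 ± 0.27 and Mpeg1 at 0.93 ± 0.19. Of the hindbrain list 13 of 21 rose (15 adjusted over the list alone, camera adjusted p = 1.15e-08, adjusted p = 0.229 with an estimated correlation). Of the telencephalon list 4 of 20 fell (8 adjusted over the list alone, camera adjusted p = 1.47e-05, adjusted p = 0.397 with an estimated correlation), and 1 rose. The mesenchymal list, of which 7 of 31 rose (10 adjusted over the list alone, camera adjusted p = 8.14e-05, adjusted p = 0.397 with an estimated correlation), included Casp1 at 1.46 ± 0.38 and the transcription factor Cebpb at 0.95 ± 0.29. Of the MAPK output genes 3 of 13 rose (7 adjusted over the list alone, camera adjusted p = 0.00215, adjusted p = 0.397 with an estimated correlation), namely Etv5 (1.05 ± 0.22), Dusp6 (0.97 ± 0.28) and Etv4 (0.59 ± 0.18). Of the endothelial markers 3 of 12 rose (7 adjusted over the list alone, camera adjusted p = 8.14e-05, adjusted p = 0.234 with an estimated correlation), with Ly6c1 at 0.97 ± 0.27, a call that was lost on the log ratio of the scanner software (adjusted p = 0.143).

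The BS result differed between batches. The mean over the hindbrain list was higher in BS than in other tumours by 2.15 in batch 2 (exact permutation, p = 0.000777) and by 1.3 in batch 3 (exact p = 5e-04). In batch 1 the difference was -0.135 (exact p = 0.788), and averaged over batches it was 1.1 (permutation, p = 0.00017). The telencephalon list gave -1.9, -1.12 and 0.496 in batches 2, 3 and 1 (exact p = 0.000777, 0.0255 and 0.278). The antigen presentation and interferon list gave 1.74, 0.864 and 0.159 (exact p = 0.000777, 0.015 and 0.548). Within batch 1 alone, 0 genes passed in limma and 25 named genes took the opposite sign, among them Nr2e1 at log2 1.44 and Thbs1 at -0.19. Within batch 2 the count was 5022 and within batch 3 it was 30. The 5 BS tumours that were not S1 all lay in batch 1, 4 of them on 2 of its 4 slides. With the labels of these slides read in reverse order 6578 genes passed, 2288 of the 2394 among them, and without their 8 tumours 6542 passed. With subtype in the model 0 genes passed for BS. With the same terms in the model, 60 of the 79 named S1 genes still passed for S1. The genes that passed thus followed the subtype label rather than the location label in this fit. Labels defined on expression would give that anyway, so the fit does not part location from subtype as a cause. For the antigen presentation and interferon list, S1 tumours outside BS exceeded the other tumours outside BS by 0.358 (exact permutation, adjusted p = 0.253). Among S1 tumours, BS exceeded the others by 0.762 (exact permutation, adjusted p = 0.0868). Neither passed, so this list was not shown to follow subtype.

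**Figure D3:**
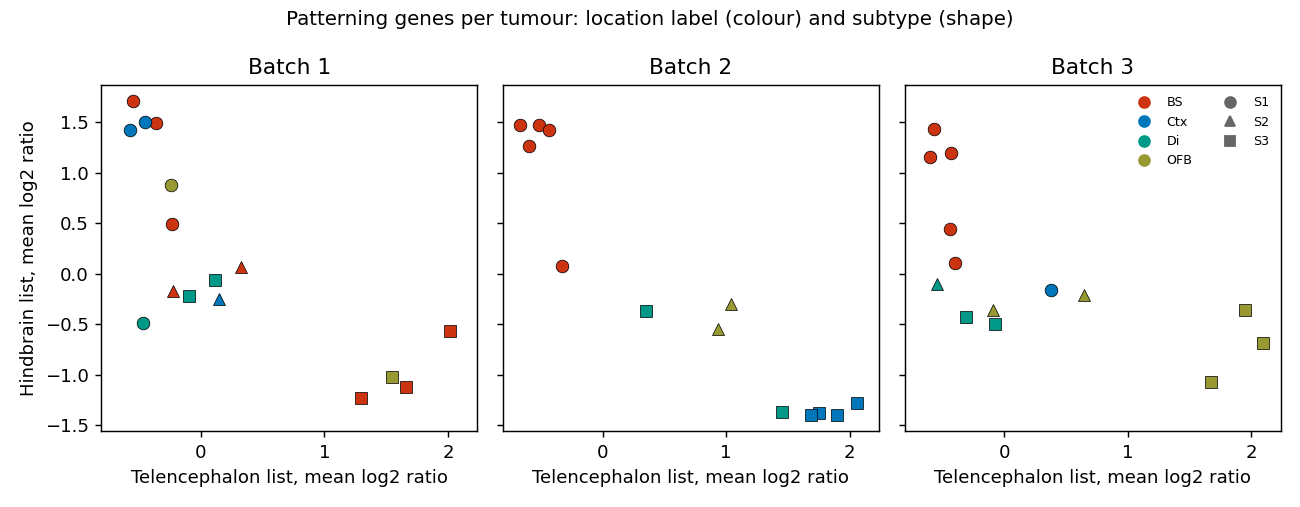
Mean log2 ratio over the telencephalon list (horizontal) and over the hindbrain list (vertical) in each tumour, 1 panel per scan batch, with location as colour and subtype as shape. In batches 2 and 3 the 10 BS tumours are all S1 and have a higher hindbrain mean than every other tumour of their batch, and in batch 1 BS tumours lie at both ends.

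The same model asked how Ctx, Di and OFB tumours differ among themselves, and 19 genes passed. Of the 16 with gene names the smallest adjusted p was that of Sec14l4, a lipid-binding protein (adjusted p = 0.000551), which was higher in Di by log2 2.05 ± 0.26 against the mean of the other 3 locations. Lhx9, a homeobox gene of the thalamus, was higher in Di tumours by 1.86 ± 0.24 (adjusted p = 5.53e-05), and Ramp3, a receptor partner protein, by 2.40 ± 0.37. Sp8, a transcription factor of olfactory bulb interneurons, was higher in OFB tumours by 3.49 ± 0.62 (adjusted p = 0.0355). The other 12 were Nr2f2, Prkcd, Smpx, Nhlh2, Gckr, Nt5dc3, Abhd12b, Wnt9b, Napepld, Acyp1, Ttc39a and Frem3. The count was 0 without the 3 dim arrays, 0 in TRPhet tumours alone and 311 with 1 tumour per mouse, so this list of genes is unsteady.

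Each location was also set against the other 3 for the gene lists. Of the diencephalon genes in Di tumours 3 of 14 rose (3 adjusted over the list alone, camera adjusted p = 0.000723, adjusted p = 0.270 with an estimated correlation), Lhx9 among them. Slc17a6, the glutamate transporter of diencephalic neurons, rose by 2.36 ± 0.45 in Di, and the neuron list averaged 0.86 (camera adjusted p = 2.57e-05, adjusted p = 0.380 with an estimated correlation). Proliferation genes were lower in Di at a mean of -0.58, where 0 of 35 fell (24 adjusted over the list alone, camera adjusted p = 3.98e-15, adjusted p = 0.358 with an estimated correlation). The lowest proliferation mean among Di tumours, -1.88, was that of TRPhet replicate 8, the dimmest array. Of the 8 Di tumours 6 were S3 and the model held no subtype term. The neuron and proliferation shifts in Di therefore cannot be told from subtype makeup. Choroid plexus genes averaged 0.86 in Di (camera adjusted p = 0.000380, adjusted p = 0.358 with an estimated correlation), with Folr1, a folate receptor of that epithelium, at 1.28 ± 0.29. Of the olfactory bulb neuron genes in OFB tumours 1 of 8 rose (6 adjusted over the list alone, camera adjusted p = 3.14e-11, adjusted p = 0.107 with an estimated correlation), namely Cdhr1, a cadherin of mitral cells, at 2.50 ± 0.46. Neuroblast genes averaged 1.01 higher in OFB (camera adjusted p = 3.57e-07, adjusted p = 0.140 with an estimated correlation). Over all genes limma called 269 in Di, 220 higher and 49 lower, and 5 in OFB, counts for which no alternative was run. Ctx tumours had 0 genes past the threshold (1079 at an unadjusted p under 0.05), and their telencephalon genes averaged 0.33 (camera adjusted p = 0.00171, adjusted p = 0.717 with an estimated correlation).

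The subtype comparisons asked which genes set each subtype apart. The subtypes are taken here as defined on the expression of these tumours, alone or together with others, so neither the counts nor the directions below are independent evidence, and the lists fixed beforehand describe them. S1 tumours (n = 18) had hindbrain and mesenchymal genes high. Thbs1 (chromosome 2, probe at 117952585 to 117952644, mm9) was higher by log2 4.07 ± 0.29 or 16.8-fold (adjusted p = 6.86e-13, 18 of 18). Ccn2, a matricellular growth factor, was higher by 3.01 ± 0.31, Hoxb2 by 3.88 ± 0.52, Pax3 by 3.62 ± 0.28, and Errfi1, a feedback inhibitor of EGFR, by 2.80 ± 0.23. The Notch target Hes5 was lower by -2.65 ± 0.22 or 6.26-fold (adjusted p = 1.21e-11, 18 of 18). Lower with it was the migrating neuroblast gene Dcx (-2.55 ± 0.21). Of the mesenchymal list 20 of 31 rose (22 adjusted over the list alone), among them Fn1, which encodes fibronectin (1.70 ± 0.18), and Tgfbi (1.63 ± 0.28). Of the hindbrain list 16 of 21 rose (17 adjusted over the list alone). Among all 351 list tests, only these calls held with an estimated correlation (camera adjusted p = 1.35e-10 for both, adjusted p = 0.0376 for both with an estimated correlation).

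Other lists in S1 moved too, but their calls did not hold with an estimated correlation. Of the antigen presentation and interferon genes 11 of 18 rose (15 adjusted over the list alone, camera adjusted p = 8.15e-07, adjusted p = 0.260 with an estimated correlation). Of the microglia and macrophage markers 14 of 20 rose (15 adjusted over the list alone, camera adjusted p = 5.70e-07, adjusted p = 0.221 with an estimated correlation), and of the T and NK cell markers 9 of 13 rose (10 adjusted over the list alone, camera adjusted p = 0.000168, adjusted p = 0.260 with an estimated correlation). Among MAPK output genes 9 of 13 rose (9 adjusted over the list alone, camera adjusted p = 0.000186, adjusted p = 0.145 with an estimated correlation), with Etv5 at 1.13 ± 0.18. Among endothelial markers 10 of 12 rose (11 adjusted over the list alone, camera adjusted p = 0.000145, adjusted p = 0.211 with an estimated correlation). Telencephalon genes went down, where 15 of 20 fell (15 adjusted over the list alone, camera adjusted p = 2.03e-07, adjusted p = 0.145 with an estimated correlation) and 1 rose, and among neuroblast genes 7 of 14 fell (9 adjusted over the list alone, camera adjusted p = 4.86e-05, adjusted p = 0.145 with an estimated correlation). In all 8096 genes passed in limma, 3935 higher and 4161 lower, and 1352, 3762 and 1827 within batches 1, 2 and 3. Genotype and location as covariates left 4927, and BS tumours alone gave 321, where Ccl5, at 1.38 ± 0.29 over all tumours, had log2 -0.08.

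S2 tumours (n = 8) had cycling and progenitor genes high and genes of neurons, astrocytes and ependyma low. Hes5 was higher by log2 2.13 ± 0.27 (adjusted p = 6.23e-07, 8 of 8). Also higher were Sfrp2, a secreted Wnt modulator, by 2.08 ± 0.19, Cdkn2a, a cell cycle inhibitor locus, by 1.91 ± 0.38 and Sox11, a progenitor transcription factor, by 1.74 ± 0.25. Stmn2, a neuronal microtubule regulator, was lower by -2.83 ± 0.49 or 7.11-fold (adjusted p = 6.78e-05, 8 of 8). With it went the lipid droplet gene Plin4 (-3.29 ± 0.43), the serotonin receptor Htr2c (-2.85 ± 0.59), the chloride transporter Slc12a5 (-2.79 ± 0.59) and the neurofilament Nefh (-2.74 ± 0.43). Of the proliferation list 23 of 35 rose (30 adjusted over the list alone, camera adjusted p = 3.41e-12, adjusted p = 0.362 with an estimated correlation), with Ccnb1 at 1.28 ± 0.28 and Bub1 at 0.98 ± 0.24, both of mitosis. Of the proneural genes 8 of 15 rose (8 adjusted over the list alone, camera adjusted p = 2.24e-05, adjusted p = 0.252 with an estimated correlation), with Pdgfra, a growth factor receptor, at 1.16 ± 0.27. Of the oligodendrocyte precursor markers, 3 of them shared with the proneural list, 8 of 14 rose (9 adjusted over the list alone, camera adjusted p = 4.08e-05, adjusted p = 0.252 with an estimated correlation), with Nkx2-2 at 1.18 ± 0.18. Of the neural list 11 of 12 fell (12 adjusted over the list alone, camera adjusted p = 3.67e-07, adjusted p = 0.272 with an estimated correlation). Of the neuron list, which shares 8 members with it, 13 of 19 fell (15 adjusted over the list alone, camera adjusted p = 4.08e-07, adjusted p = 0.362 with an estimated correlation). Ependymal markers fell too, where 6 of 8 fell (7 adjusted over the list alone, camera adjusted p = 8.66e-06, adjusted p = 0.252 with an estimated correlation). Of the astrocyte markers 8 of 20 fell (10 adjusted over the list alone, camera adjusted p = 0.000179, adjusted p = 0.448 with an estimated correlation), with the gap junction gene Gja1 at -1.94 ± 0.36. Mature oligodendrocyte markers made no call (-0.26, camera adjusted p = 0.208). Among microglia and macrophage markers 8 of 20 fell (8 adjusted over the list alone, camera adjusted p = 0.000572, adjusted p = 0.434 with an estimated correlation). In all 6426 genes passed in limma, 2767 higher and 3659 lower, a split that the log ratio of the scanner software turned to 3723 and 2825. Within batches 1, 2 and 3 the counts were 1165, 296 and 393, and 1 tumour per mouse gave 2781.

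S3 tumours (n = 17) had the genes of neurons and mature glia high and those of cycling cells low. Rasgrp1 was higher by log2 3.68 ± 0.30 or 12.8-fold (adjusted p = 6.88e-12, 17 of 17) and Slc12a5 by 3.44 ± 0.52. The inhibitory receptor subunit Gabrd was higher by 2.93 ± 0.39, and the sodium channel subunit Scn2b by 3.06 ± 0.39. Hoxa3 was lower by -2.93 ± 0.33 or 7.60-fold (adjusted p = 1.42e-08, 17 of 17). Lower with it were Ms4a7, a macrophage gene (-2.72 ± 0.33), Aldh1a3 of retinoic acid synthesis (-2.42 ± 0.43), the endothelial gene Esm1 (-2.34 ± 0.51) and Thbs1 (-2.20 ± 0.30). Among neuron markers 19 of 19 rose (19 adjusted over the list alone, camera adjusted p = 1.67e-11, adjusted p = 0.126 with an estimated correlation), and in the neural list 12 of 12 rose (12 adjusted over the list alone, camera adjusted p = 7.96e-10, adjusted p = 0.126 with an estimated correlation). Examples were Stmn2 at 2.86 ± 0.42 and Syt1 of synaptic vesicles at 2.40 ± 0.39. Markers of other cell types rose beside them. Among astrocyte markers 12 of 20 rose (13 adjusted over the list alone, camera adjusted p = 4.40e-05, adjusted p = 0.410 with an estimated correlation), among mature oligodendrocyte markers 11 of 16 rose (13 adjusted over the list alone, camera adjusted p = 0.000264, adjusted p = 0.330 with an estimated correlation), and among ependymal markers 8 of 8 rose (8 adjusted over the list alone, camera adjusted p = 0.000104, adjusted p = 0.188 with an estimated correlation). Of the proliferation list 30 of 35 fell (32 adjusted over the list alone, camera adjusted p = 6.86e-14, adjusted p = 0.188 with an estimated correlation), with Ccnb1 at -1.10 ± 0.24. Of the MAPK output list 12 of 13 fell (12 adjusted over the list alone, camera adjusted p = 3.13e-07, adjusted p = 0.0580 with an estimated correlation), with Spry1 at -1.85 ± 0.29 and Dusp6 at -1.45 ± 0.19, both feedback inhibitors of that pathway. Of the hindbrain list 17 of 21 fell (19 adjusted over the list alone, camera adjusted p = 1.49e-08, adjusted p = 0.102 with an estimated correlation). Of the telencephalon list 15 of 20 rose (17 adjusted over the list alone, camera adjusted p = 5.00e-08, adjusted p = 0.126 with an estimated correlation). In all 10530 genes passed in limma, 5904 higher and 4626 lower, a split that the log ratio of the scanner software turned to 4915 and 6238. Within batches 1, 2 and 3 the counts were 1668, 4208 and 4151.

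**Figure D4:**
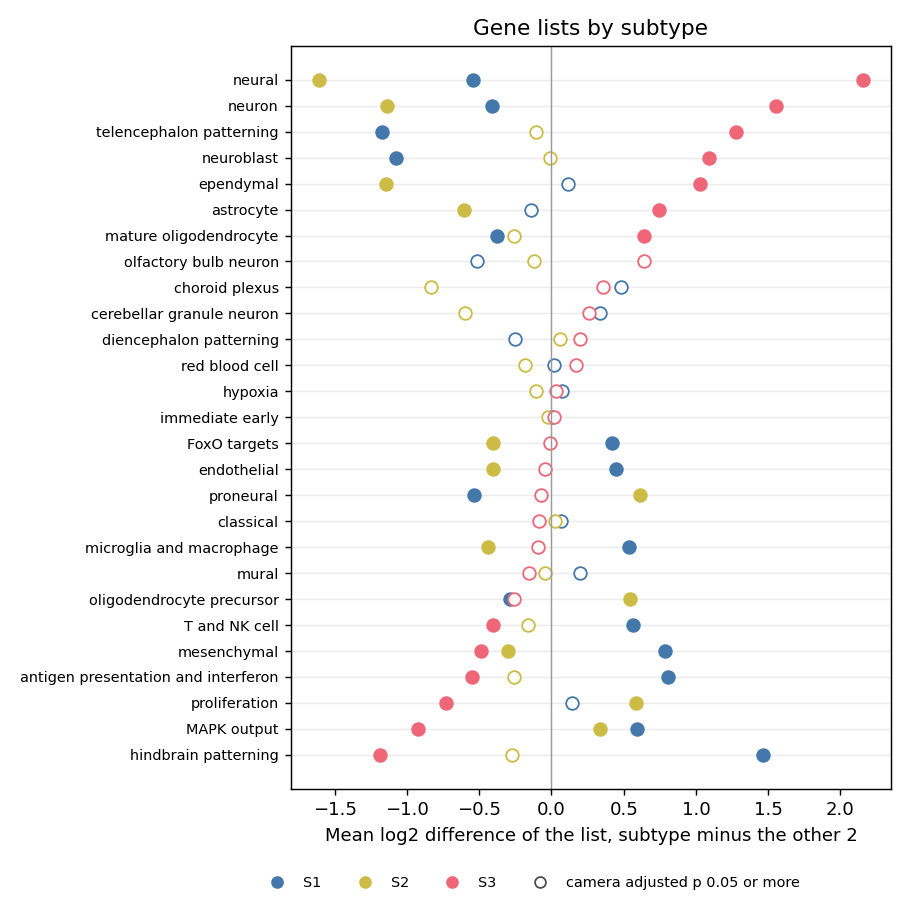
Mean log2 difference over the genes of each of 27 lists, each subtype minus the mean of the other subtypes; open circles mark a camera adjusted p of 0.05 or more with the preset correlation. The neural list spans from -1.61 in S2 to 2.16 in S3, and the hindbrain list from -1.19 in S3 to 1.46 in S1.

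Diagnosis and survival asked whether expression goes with grade or with the survival of the mouse, beyond genotype and location. For GBM against A3 tumours (n = 31 and 12) limma called 0 genes, with 918 at an unadjusted p under 0.05 against 1400 by chance. The smallest p belonged to Gpatch11 at log2 0.26 ± 0.06 (adjusted p = 1.00), whose probes disagreed in sign, Gxylt1 at 0.32 ± 0.08, Retnlg, a neutrophil gene, at 0.67 ± 0.19 and the crystallin Cryaa at -0.23 ± 0.06. Proliferation genes averaged 0.21 higher in GBM, with 0 of 35 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 4.89e-05, adjusted p = 0.883 with an estimated correlation). Along survival limma again called 0 genes, with 1409 at an unadjusted p under 0.05. The smallest p belonged to Gsap at log2 -0.74 ± 0.16 per month (adjusted p = 0.849), Slc15a4, a lysosomal transporter, at -0.58 ± 0.13, Brca1 of DNA repair at -0.63 ± 0.14 and Becn1 of autophagy at -0.32 ± 0.07. Proliferation genes averaged -0.32 per month of survival (camera adjusted p = 8.56e-10, adjusted p = 0.702 with an estimated correlation). Neuron markers averaged 0.50 (camera adjusted p = 0.00185, adjusted p = 0.702 with an estimated correlation) and astrocyte markers 0.36 (camera adjusted p = 0.00182, adjusted p = 0.702 with an estimated correlation), with 0 genes of these 3 lists past the threshold adjusted over the list alone.

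A further model of the 35 TR and TRPhet tumours asked whether the BS difference depends on the genotype. Limma called 0 genes, with 2273 at an unadjusted p under 0.05. The smallest p belonged to Smarcd1, a chromatin remodeller subunit, at log2 -1.07 ± 0.21 (adjusted p = 0.289), Zfp974 at -1.01 ± 0.21, the noncoding RNA gene Morrbid at 2.91 ± 0.63 and Bcl11b, a transcription factor of forebrain neurons, at -4.75 ± 1.05. Telencephalon genes had a BS difference lower in TRPhet than in TR tumours by -2.96, with 0 genes past the threshold over all genes and 12 of 20 adjusted over the list alone (camera adjusted p = 1.46e-14, adjusted p = 0.0678 with an estimated correlation). Neuroblast genes, of which 6 are also in that list, differed by -2.59, with 6 of 14 adjusted over the list alone (camera adjusted p = 7.79e-09, adjusted p = 0.0678 with an estimated correlation). The 6 TR tumours in BS were all in batch 1 and 4 of them lay on its 2 slides named above, so genotype, batch and slide are confounded here. Outside BS the TR tumours were 2 in Di and 1 in Ctx, all in batch 3, and the TRPhet tumours 7 in OFB, 5 in Ctx and 3 in Di. The model did not tell these locations apart, so the location makeup of the other tumours is confounded with genotype too.

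The last question was whether tumours of the same mouse resemble each other. Over the 7 mice with 2 tumours, the correlation across genes of the batch- and location-adjusted log ratios averaged 0.185, against -0.0183 for pairs redrawn among tumours of the same genotype (one-sided permutation test, p = 0.0259), and it ran from -0.448 to 0.674 over the pairs. Genes are not independent replicates, so the pairs are the units of this test. Without the 2 pairs that fail the label check below it averaged 0.285 over 5 pairs (permutation, p = 0.0046), a setting chosen after the values were seen. The subtype was shared by 3 of the 7 pairs, against a mean of 2.45 in redrawn pairs (permutation, p = 0.468). As a check of the labels, 2 of the 7 pairs did not match for sex-linked genes.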

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

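Chosen only after the result was seen were the tests of scan batch in batches 2 and 3, labels of 2 slides in reverse order, a mislabelled sample, and, for S3, scan batch, dim arrays and location and genotype. In 553 groups of 4 to 10 tumours, each list mean or named gene was checked for 1 tumour far from the rest, as the gap to its nearest neighbour divided by the group's range. This picked out 41 groups, where chance alone gives about 1 in 20, or 27.6, so most such gaps need no cause. In OFB, TRPhet replicate 4 stood apart, high for Hoxb2 (0.826), Hoxb4 (0.792), Hoxb3 (0.778), Nhlh2 (0.706), Pax3 (0.705), Thbs1 (0.658) and the hindbrain list (0.558), and low for Nr2e1 (0.749), Ptpn5 (0.554) and Sox11 (0.51). It is an S1 tumour on 1 of the 2 slides of batch 1 read in reverse order above, as is TRPhet replicate 5 of Di, named next. Their gaps cannot be told from a wrong location label. In Di, TRPhet replicate 8, the dimmest array, was high for Hoxb2 (0.65), Hoxb3 (0.582) and Hoxb4 (0.566), TRPhet replicate 5 for Casp4 (0.657), and TRPhet replicate 15 was low for the hindbrain list (0.673) and high for the telencephalon list (0.55). TR replicate 7 was low in Di for the neural list (0.586) and Acyp1 (0.571), and low in S2 for Ddit4 (0.624).

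In S2, TR replicate 5 was high for the T and NK cell list (0.757), Gzma (0.744), Ccl5 (0.696), Cd2 (0.609), Cd3d (0.573), Mal2 (0.668), Htr2c (0.662) and Hoxb4 (0.571). TRPhet replicate 18 was high in S2 for Car6 (0.839) and Trf (0.537) and low for Tspan2 (0.563), TRPnull replicate 5, a dim array, was high for Camk2a (0.577) and TRPhet replicate 2 for Kif20a (0.632). Among TRPnull tumours replicate 4 was high for the T and NK cell list (0.6) and the antigen presentation and interferon list (0.566). Among TR tumours replicate 3 was high for the microglia and macrophage list (0.623), replicate 4 for the olfactory bulb neuron list (0.735) and replicate 9 for Rb1 (0.529). TR replicate 4, labelled BS, lies on the other of the 2 slides read in reverse order above. In Ctx, TRPhet replicate 9 was high for the diencephalon list (0.536) and TRPhet replicate 12 low for Emcn (0.538). In OFB, TRPnull replicate 8 was low for Abhd12b (0.511) and TRPhet replicate 21 high for Frem3 (0.516). The BS difference also differed between TRPhet and TR tumours, by a test of the difference itself, for the telencephalon list at -2.96 and the neuroblast list at -2.59 (fry adjusted p = 0.0143 for both, adjusted p = 0.0678 for both with an estimated correlation). The 6 TR tumours in BS were all in batch 1, 4 of them on the 2 slides read in reverse order. The TR tumours outside BS were 2 in Di and 1 in Ctx, with 0 in OFB, where 7 TRPhet tumours lay. Genotype, batch, slide and the location makeup of the tumours outside BS are thus confounded in this test.

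Hindbrain genes were higher in BS tumours in batches 2 and 3. The difference was at least 1.3 within each, which scan batch alone cannot give. In batch 1 it was -0.135, so the test over all batches does not decide. Yet within batch 1 the hindbrain list was higher in S1 than in other tumours by 1.51 (exact permutation, p = 0.000612). This argues against a batch effect that hides these genes there, though the subtypes are taken as defined on expression. What batch 1 lacked was their tie to the location label. RNA from surrounding brainstem would not raise these genes outside BS, yet S1 tumours outside BS were higher than others outside BS by 1.3 (exact permutation, p = 0.000922); 4 of these 5 tumours are in batch 1, where the location labels are in doubt, so this test does not decide. Among tumours that are not S1, BS tumours were higher by 0.0619 (exact p = 0.803), so the subtype makeup of the BS tumours cannot be told apart from location, all 5 such BS tumours being in batch 1. A candidate explanation is that the labels of 2 slides in reverse order of array position were recorded in batch 1: read the other way, the tumours match for sex-linked genes in 7 of 7 mice (5 as deposited), but only 1 of the 2 slides holds tumours of such mice, so nothing apart from the location genes themselves bears on the other slide, and 17 of 18 BS tumours being S1 or a hindbrain difference of 1.41 in batch 1 under that reading restates the values that prompted it. Of the TR tumours in BS, 0 of 4 on these slides and 2 of 2 on the other slides of batch 1 were S1, but 6 tumours are too few to settle an effect of genotype, which stays open.

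Neuron and glial markers were higher together in S3 tumours, and scan batch alone is argued against by a neuron list difference of at least 1.09 within each batch (exact permutation, p = 0.0139 in batch 1, 0.00291 in batch 2 and 5e-04 in batch 3), though not as clearly for glia (mature oligodendrocyte list 0.455, p = 0.0709 in batch 1, and astrocyte list 0.441, p = 0.0991 in batch 2). Of the 10530 genes, 9543 passed both with all arrays and without the 3 dim ones, and 9008 both with and without location and genotype as covariates. These counts argue against dim arrays, or location and genotype, as the whole cause. They are a weak test, since they cover all genes and the subtypes are taken as defined on expression. Of the dim arrays, only TRPhet replicate 8 is an S3 tumour. RNA from surrounding brain could raise these markers. The list means were correlated after batch was taken out over all tumours. The neuron and mature oligodendrocyte list means rose together within S1 (Pearson r = 0.882, rho = 0.911, n = 18, permutation, adjusted p = 9e-05 and 6e-05). They also did within S3 (r = 0.735, rho = 0.615, n = 17, permutation, adjusted p = 0.00162 and 0.0115). In S1 and S3, r stayed at 0.863 and 0.592 without the 2 tumours farthest from the median. Neuron and proliferation means went apart (r = -0.663 in S1 and -0.481 in S3, rho = -0.585 and -0.686, permutation, adjusted p = 0.00301 and 0.0498 for r, 0.0115 and 0.0056 for rho; r = -0.611 and -0.44 without the 2 farthest tumours), and Syt1 averaged a log2 ratio to the reference of 4.81 in S3 against 2.41 in S1, and Mal 3.44 against 2.68. Astrocyte markers can also come from the tumour cells, so a tumour that keeps more differentiated cells stays open and was not tested.

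In 2 of the 7 mice with 2 tumours the pair lay on opposite sides for sex-linked genes, which a mislabelled sample would give, and 2 is the count of such mice as deposited. With the labels of 2 slides in reverse order the count of matching mice was 7, but both unlike pairs involve the same slide, and an exchange of single tubes on it was not tested against the reversed order, nor was a loss of sex chromosomes in a tumour, so these stay open. No biological explanation from the design was tested for it.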

How the results depend on the processing

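Settings chosen only after the data were seen were labels of 2 slides in reverse order, without the 8 tumours of these 2 slides, without the 3 dim arrays, the 2 pairs unlike in sex as 4 mice and without the 2 pairs unlike in sex. Over 239 alternatives of the main results, 192 kept the direction and side of the threshold, or a count within 1.5 times, and 47 did not. Named genes past the threshold kept their direction in 5898 of 5937 values and passed again in 5030, leaving out the test among Ctx, Di and OFB, which has no direction. Counts for diagnosis, survival and the dependence of BS on genotype were 0 under every alternative run. For the changes below the cause was not tested, except that single batches, 1 tumour per mouse and single groups hold fewer tumours. Not run, for want of tumours, were TRPnull and TRPhet against TR within batch 2, differences among Ctx, Di and OFB within batch 3, and the dependence of BS on genotype within batches 1, 2 and 3. No alternative was run for the counts of Ctx, Di or OFB against the other 3 locations. By replicate number, no paired analysis was possible because these numbers only count the tumours within a genotype. The 7 mice with 2 tumours share a block in the gene tests unless a setting changes the block, but only 3 of these pairs hold a BS tumour, and locations were not compared within mice. Signal over background limits the dim arrays.

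For TRPnull against TR the count of genes was 2 with 1 tumour per mouse, 1 with no batch term, 2 within batch 3, 3 with subtype as a covariate, 1 with the slides reversed and 1 without their 8 tumours. For TRPnull against TRPhet it was 6 within batch 3 and 1 with subtype. For TRPhet against TR it was 2 on the log ratio of the scanner software, 0 with no batch term, 0 within batch 1, 3 within batch 3, 0 without location and 6 with subtype. It was 0 in BS tumours only, 0 with the slides reversed and 0 without their tumours. For BS it was 0 within batch 1, 5022 within batch 2, 30 within batch 3, 0 with subtype as a covariate and 1205 in TRPhet tumours only. It was 6578 with the slides reversed (2288 of the 2394 shared), 6542 without their tumours (2367 shared) and 1578 without the dim arrays. Among Ctx, Di and OFB it was 311 with 1 tumour per mouse, 1 within batch 1, 77 within batch 2, 53 with subtype, 0 in TRPhet tumours only, 7 with the slides reversed and 0 without the dim arrays. For S1 it was 1352, 3762 and 1827 within batches 1, 2 and 3, 4927 with genotype and location and 321 in BS tumours only. For S2 it was 2781 with 1 tumour per mouse and 1165, 296 and 393 within the batches. For S3 it was 1668, 4208 and 4151. Of 139 list calls, 2 held with an estimated correlation, and fry made 63 calls in all. The difference of TRPhet from TR mice in survival was -0.43 months between medians.

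With the slides reversed, list means turned sign: in TRPnull against TR telencephalon to 0.16 and neuroblast to 0.27. In TRPhet against TR they turned for proneural to 0.17, hindbrain to -0.15, telencephalon to 0.28, diencephalon to 0.14 and neuroblast to 0.23. Rb family genes and Trp53, none past the threshold, turned as follows. In TRPnull against TR, Rbl2 was 0.35 within batch 3, 0.10 with the slides reversed and 0.12 without their tumours. Trp53 was -0.29 within batch 3, -0.063 without location, -0.0014 with subtype, -0.14 with the slides reversed and -0.19 without their tumours. In TRPnull against TRPhet, Trp53 was 0.0605 on the scanner log ratio, 0.046 in the deposited table, 0.0596 with 1 tumour per mouse, 0.037 within batch 1, 0.14 within batch 2 and 0.0245 with subtype. There Rbl2 was 0.046 within batch 1 and 0.17 within batch 3, and Rb1 -0.092 within batch 2. In TRPhet against TR, Rbl2 was -0.0226 in the deposited table, -0.0114 with no mouse block, -0.0121 with slide as block, -0.0815 with 1 tumour per mouse, -0.32 within batch 1, -0.32 in BS tumours only and -0.031 without location. Rbl1 was 0.00498 with no mouse block, 0.0063 with slide as block, 0.083 with 1 tumour per mouse, 0.0485 with the slides reversed and 0.0617 without the dim arrays. Trp53 was -0.0164 within batch 3, -0.026 with subtype, -0.0723 with the slides reversed and -0.15 without their tumours.

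For BS within batch 1, Car6 was -0.72, Thbs1 -0.19, Plac8 -0.66, Celf3 0.25, Tmeff1 0.91, Nrn1 0.63, Ptpn5 1.23, Kcnd2 0.24. There also Casp1 was -0.10, H2-K1 -0.10, Psmb9 -0.10, B2m -0.40, Psmb8 -0.30 and Nr2e1 1.44. The same setting put Ctss at -0.36, Mpeg1 at -0.34, Fcer1g -0.24, Ly86 -0.059, Ccl5 -0.27, Cd2 -0.31, Gzma -0.25, Cd3d -0.43, Tspan2 0.37, Sox11 0.71 and Ly6c1 -0.51. For BS, Hoxa3 was -0.56 within batch 3 and Nr2e1 0.064 with subtype. For S1, Foxm1 was -0.051 within batch 1, and Pik3ip1 -0.12 and Ccl5 -0.084 in BS tumours only. For S2, Hoxb3 was 0.15 in the deposited table and 0.054 at 22 arrays above background, Barhl1 -0.11 with the mean of all probes, and Gjb6 0.0702 and Zic1 0.25 within batch 2. For S3 within batch 2, Neu4 was -0.0677, Slco1a4 -0.10, Cdhr1 -0.36 and Doc2g -0.48.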

Other observations

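Choroid plexus genes were lower in OFB tumours at a mean of log2 -0.80, with 0 of 7 past the threshold over all genes and 4 adjusted over the list alone (camera adjusted p = 8.97e-05, adjusted p = 0.239 with an estimated correlation). Mural cell markers averaged 0.19 higher in BS (camera adjusted p = 0.0604) and red blood cell genes, of which 2 were measured, 0.66 per month of survival (camera adjusted p = 0.0136, adjusted p = 0.702 with an estimated correlation). Hypoxia genes averaged 0.22 per month of survival (camera adjusted p = 0.00476, adjusted p = 0.702 with an estimated correlation), with 0 of 18 past the threshold over all genes and 0 adjusted over the list alone. FoxO targets were at -0.00 in TRPnull against TR tumours (camera adjusted p = 0.748). In S1 their mean was 0.42, where 6 of its 12 genes rose (6 adjusted over the list alone) (camera adjusted p = 0.0165, adjusted p = 0.347 with an estimated correlation). Immediate early genes were at -0.26 in TRPnull against TRPhet tumours (camera adjusted p = 0.0295, adjusted p = 0.579 with an estimated correlation). The classical list (0.06 in S1, camera adjusted p = 0.388) and the cerebellar granule neuron list (0.34, camera adjusted p = 0.212) made no call in any contrast. Of the lists, camera's direction for the hindbrain list in S2 was up, against a mean of -0.28 (adjusted p = 0.974).

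Whole chromosomes shifted little after genotype, location and batch were taken out. Of 860 medians of a chromosome in a tumour, 189 differed from random gene sets of the same size, 83 higher and 106 lower, but the largest shift was log2 0.127 and 0 reached 50% of the log2 shift that 1 extra copy in all cells would give. The count was 186 on the log ratio of the scanner software (largest shift 0.206) and 168 without genotype and location (largest shift 0.171), again with 0 of that size.

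Other splits of the tumours bear on each count. The 2394 genes of BS were matched by 1 of 100 splits, the real one (highest other 676), which is the smallest share that 100 splits can give. It argues against chance for that count. The share was not adjusted over the comparisons, and the splits moved the location labels freely across batches and mice. The 8096 of S1 (highest other 1), 6426 of S2 (128) and 10530 of S3 (31) were matched by 1 each, which is no test of chance for groups taken as defined on expression. The 19 genes that differed among Ctx, Di and OFB were matched by 4 of 100, the real one included (highest other 252). That share was not adjusted over the comparisons and other splits called more genes, so chance is not excluded there. A split that calls several times the real count points to some structure of the samples, which was not looked into. For Pcdh19, the 1 gene of TRPhet against TR, 6 of 100 splits gave as many and the highest other 44, so chance is not excluded, and here too the highest split is several times the real count. With 0 genes in TRPnull against TR (highest other 2), TRPnull against TRPhet (490, which points to some structure too), diagnosis (58), survival (2) and the dependence of BS on genotype (24), all 100 splits gave as many.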
